A study of Mus musculus with 4 samples.

How the data were processed

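RNA was measured in oligodendrocytes sorted as O4 and GalC double-positive cells from mouse cortex at postnatal day 5, in 2 wild-type libraries (WT) and 2 libraries from mice homozygous for a Zfp488 knock-in allele, labelled knockout (KO). The labels record the cells once as a cell line, although the series describes cells sorted from tissue. Per the labels' protocols, total RNA was extracted with the RNeasy Micro Kit and libraries were prepared with an Illumina RNA-seq kit. The submitters' processing notes name TopHat, with no version, and the mm10 genome build. The deposited values are FPKM, 1 column per library, written to 3 decimals. The program that estimated them, the gene annotation, the strand setting and any filter are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of a host gene can be assigned to a small RNA inside it.

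FPKM are not counts, and total reads are not given in the sources used here. Low values were examined for steps of whole reads, after the tests had been run. For genes at 0.02 to 0.2 FPKM in both libraries of a pair, between 3.82% and 4.66% of the ratios fell in a single bin of 0.02 on the log2 scale, against at most 2.21% with genes shuffled. The ratios at those bins give what 1 read was worth in a library relative to WT 1, namely 0.853 in WT 2, 0.927 in KO 1 and 0.953 in KO 2, so WT 2 was the deepest library. Multiplied by the longest annotated transcript, the values gathered at 0.0263, 0.0229, 0.0245 and 0.0263 FPKM per read on 1 kb in WT 1, WT 2, KO 1 and KO 2, and again at double those values. These figures are approximate because the transcript lengths used for FPKM are not given. Counts per gene were not rebuilt, and no interval for counting error is given. The table held 35869 rows, of which 12972 were at 0 in all 4 libraries. Some genes that oligodendrocytes normally use, such as Ndrg1, were listed at 0 in every library, so a 0 can be a failed estimate. Some rows were listed below 0.05 FPKM in a single library with at least 5 FPKM in each of the others. They numbered 10 in WT 1, 11 in WT 2, 2 in KO 1 and 3 in KO 2. Such rows were thus more frequent in the WT libraries. Names of 27 rows had the form of a date, as spreadsheet programs make them, and 18 of these were tested under that name. Another 2 symbols stood on 4 rows, each of which was tested.

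Values were analysed as log2(FPKM + 1), with no further scaling. A fold change on this scale understates the change of genes with low FPKM. The 10754 rows with an FPKM of at least 1 in at least 2 of the 4 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model with genotype, empirical Bayes variances with a mean-variance trend, Benjamini-Hochberg adjustment, threshold 0.05 on the adjusted p). Errors given as SE are those of the log2 fold change from this model, and values as mean ± SD are FPKM over the libraries of a group. All p-values are two-sided.

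Gene lists, 31 in number, were written before the data were examined, as were the tests, the rule for named genes and the alternatives, apart from those said below to have been added. The 28 lists with at least 5 tested members were tested with camera, a competitive test in limma, with the correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over the lists. The lists were also tested with a correlation estimated from the data, with fry, and against 10000 random lists of the same size matched on mean FPKM in 20 bins. A maturation index was computed per library as the mean of the 30 tested myelin genes minus that of the 33 tested precursor genes, and compared with an exact permutation test over the 6 assignments of the 4 libraries. That test cannot give a p below 0.333.

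Named genes were chosen by a fixed rule. Zfp488 came first, then 12 higher and 12 lower genes past the threshold with both KO libraries beyond both WT libraries and a mean of at least 2 FPKM in the higher group. As 0 genes passed by limma, with 608 at an unadjusted p under 0.05, the places were filled by the smallest unadjusted p among the 1390 higher and 1531 lower genes that met the remaining conditions. Unnamed genes, pseudogenes and histone genes were skipped, which passed over 5 rows. From each list up to 4 members past the threshold were named, or up to 2 with the largest absolute log2 fold change where none passed. Mbp, Mag, Mog, Cnp, Myrf, Sox10, Olig1, Olig2, Nkx2-2, Pdgfra, Cspg4, Enpp6, Gpr17 and Mki67 were always named. Genes named for a difference between library numbers, and Xist and Sostdc1, were chosen after their values were seen. Some genes that the rule names are not reported here.

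Symbols and neighbouring genes came from RefSeq GRCm38.p6, which held the symbols of 10122 tested rows. Transcript length and GC content were those of the longest transcript of each gene in the GENCODE M21 annotation of GRCm38. A length was found for 10093 tested rows (93.9%). The Zfp488 gene model came from the same GENCODE annotation. Trends with transcript length, expression level and GC content were removed from each library's deviation by loess with a span of 0.4. Of 315 tested small RNA rows, 219 microRNA and small nucleolar RNA rows lay within exactly 1 other tested gene, taken by position as the host. Intervals for list medians are bootstrap 95% intervals from 10000 draws over genes, which reflect the spread between genes and not between replicates. The interval for the mean difference of Olig1, Olig2 and Sox10 is a 95% t interval over the libraries.

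The tests were checked on data simulated for this comparison with 10754 genes, 200 of them changed, in 20 simulations. The gene test called 0.373% of genes changed by 1 on the log2 scale, 4.48% of those changed by 2 and 16.8% of those changed by 3, with 0.75 false calls per simulation. For gene lists, 1 of 28 lists of 30 genes was shifted by 0.5 in each of 20 simulations with independent genes, and in each of 20 more with a correlation of 0.13. Camera called 100% and 95% of these shifted lists, and 0.185% and 12.6% of the unshifted lists. With an estimated correlation it called 0% of the shifted lists in either case, so a missed call by that test says little about a shift of this size.

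Alternatives changed the pseudocount (0.1 or 0.5), the filter (none, or 5 FPKM), the scaling (TPM, median ratio or quantile normalization), the variance model, the library weights, the threshold, the use of the replicate number as a block, and left out each library in turn. Added after seeing the data were fits without small RNA rows, without the genes of 6 other lists (cell cycle, endothelial, red blood cell, choroid plexus, immediate early and fibroblast), and with the trends in length, level, both or GC content removed.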

Results

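Gene expression was measured by RNA sequencing in oligodendrocytes, the myelin-forming glia of the central nervous system, taken from the cerebral cortex of mice at postnatal day 5. Cells positive for both O4 and GalC, lipid antigens on the surface of late precursors and differentiating oligodendrocytes, were collected by fluorescence-activated sorting. The 4 libraries form 2 groups of 2: wild type (WT) and mice homozygous for a knock-in allele of Zfp488, which the labels call Zfp488 knockout (KO). Zfp488 encodes a zinc finger protein enriched in the oligodendrocyte lineage. The comparison asks which transcripts of sorted oligodendrocytes differ when Zfp488 is disrupted, in a study concerned with the timing of myelination. Values are FPKM, read fragments normalized to transcript length and to the number of mapped fragments, for 35869 gene rows, and they sum to between 311846 (KO 1) and 341145 (WT 2) per library. Total reads are not given, but low values stepped by whole reads. On a transcript of 1 kb, 1 FPKM stood for about 38.1 reads in WT 1, 43.7 in WT 2, 40.8 in KO 1 and 38.1 in KO 2, so the genotypes did not separate by depth. Between 9902 rows (WT 1) and 10541 rows (KO 2) had an FPKM of 1 or more. Spearman's correlation between libraries across all rows lay between 0.859, for the 2 WT libraries, and 0.884, for the 2 KO libraries. Nothing in the labels says that the libraries of a group came from separate animals, so the tests measure only the spread between these libraries, which may be technical.

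Zfp488 itself was read at 6.61 and 5.29 FPKM in WT 1 and WT 2, and at 4.82 and 4.11 FPKM in KO 1 and KO 2. The log2 fold change of KO over WT was -0.34 (SE 0.33), which did not pass the test (limma, adjusted p = 0.95). In the reference annotation (GRCm38) the gene lies on chromosome 14, from 33967070 to 33978764 on the minus strand, with 2 exons. Its coding sequence of 1011 bp (33970194 to 33971204) lies within a single exon, and 76.5% of its 4301 bp of exon sequence is untranslated. The design of the knock-in allele is not given in the sources used here, and reads from any part of the locus that remains would still be counted, so these values check the labels only weakly.

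Myelin genes as a list were lower in the KO libraries and oligodendrocyte precursor genes were higher, by camera with a preset correlation. Neither list passed by camera with an estimated correlation (adjusted p = 0.628 for each). Mbp, which encodes a main structural protein of compact myelin, was at 88.6 ± 20.5 FPKM in WT and at 47.3 ± 25 FPKM in KO (mean ± SD, n = 2), a log2 difference of -0.97 (SE 0.42). Pdgfra, the receptor for the precursor mitogen PDGF-AA, went the other way, from 22.6 ± 5.87 to 41.4 ± 1.62 FPKM (log2 difference 0.86, SE 0.26). No single gene passed the test: of 10754 genes, 0 had an adjusted p under 0.05 by limma (smallest 0.859), while 608 had an unadjusted p under 0.05 (302 higher and 306 lower), against 537.7 by chance. With the libraries rescaled to TPM that split was 383 higher and 181 lower, and the median gene moved by 0.095 on the log2 scale. The statements on lists therefore rest on many small differences, and the values given for single genes are differences that did not pass.

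Of 30 tested genes in the list of myelin and mature oligodendrocyte genes, both KO libraries lay below both WT libraries for 11, above for 2, and the groups overlapped for 17. The list fell with a median log2 fold change of -0.59 (camera adjusted p = 3.3e-06; adjusted p = 0.628 with an estimated correlation). Mog, which encodes a protein of the outer myelin surface and is switched on late in maturation, was at 17.0 and 7.77 FPKM in WT and at 5.43 and 0.758 FPKM in KO (log2 difference -1.90, SE 0.74). Mag, an adhesion protein facing the axon, differed by -1.5 (SE 0.74), and Cnp, an enzyme of non-compact myelin, by -0.65 (SE 0.42). Without WT replicate 1 the list no longer passed (median -0.33, adjusted p = 0.19).

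The 28 tested genes of premyelinating and newly formed oligodendrocytes also fell as a list, by a median of -0.41 (camera adjusted p = 0.0010; adjusted p = 0.815 with an estimated correlation). Both KO libraries were lower for 7 of them, higher for 0, and 21 overlapped. Enpp6, a marker of newly forming oligodendrocytes, was at 44.3 ± 9.72 FPKM in WT and 22.6 ± 14.3 FPKM in KO (SD, n = 2; log2 difference -1.07, SE 0.49), and the long non-coding RNA 9630013A20Rik was at 92.9 ± 42.9 and 37.8 ± 25.2 FPKM. Gpr17, a receptor of committed precursors, did not share this difference (126.6 ± 54.9 FPKM in WT, 129.0 ± 74.4 in KO; log2 difference -0.03, SE 0.51), and its sign turned under 5 of the alternatives. The list no longer passed without WT replicate 1 (median -0.15, adjusted p = 0.379) or without KO replicate 2 (median -0.068, adjusted p = 0.78).

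Among 33 precursor genes, both KO libraries were higher for 17, lower for 0, and 16 overlapped. The list rose by a median of 0.35 (camera adjusted p = 1.1e-05; adjusted p = 0.628 with an estimated correlation). Over the alternatives the median lay between 0.19, without WT replicate 1, and 0.45, with the libraries rescaled to TPM. Susd5 was at 5.24 and 1.34 FPKM in WT and at 27.3 and 13.8 FPKM in KO (log2 difference 2.42, SE 0.61), and the membrane-bound metalloproteinase gene Mmp15 was at 32.8 ± 8.96 and 73.3 ± 21.6 FPKM. Cspg4, which encodes the NG2 proteoglycan of precursors, was at 26.5 ± 1.89 FPKM in WT and 37.6 ± 6.45 FPKM in KO (SD, n = 2; log2 difference 0.48, SE 0.24). The maturation index, the mean log2(FPKM + 1) of the myelin list minus that of the precursor list, was -0.971 ± 0.376 in WT and -2.02 ± 0.131 in KO (SD, n = 2). Both KO libraries lay below both WT libraries and the difference was -1.05, for which an exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Without WT replicate 1 the difference was -0.64.

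**Figure D1:**
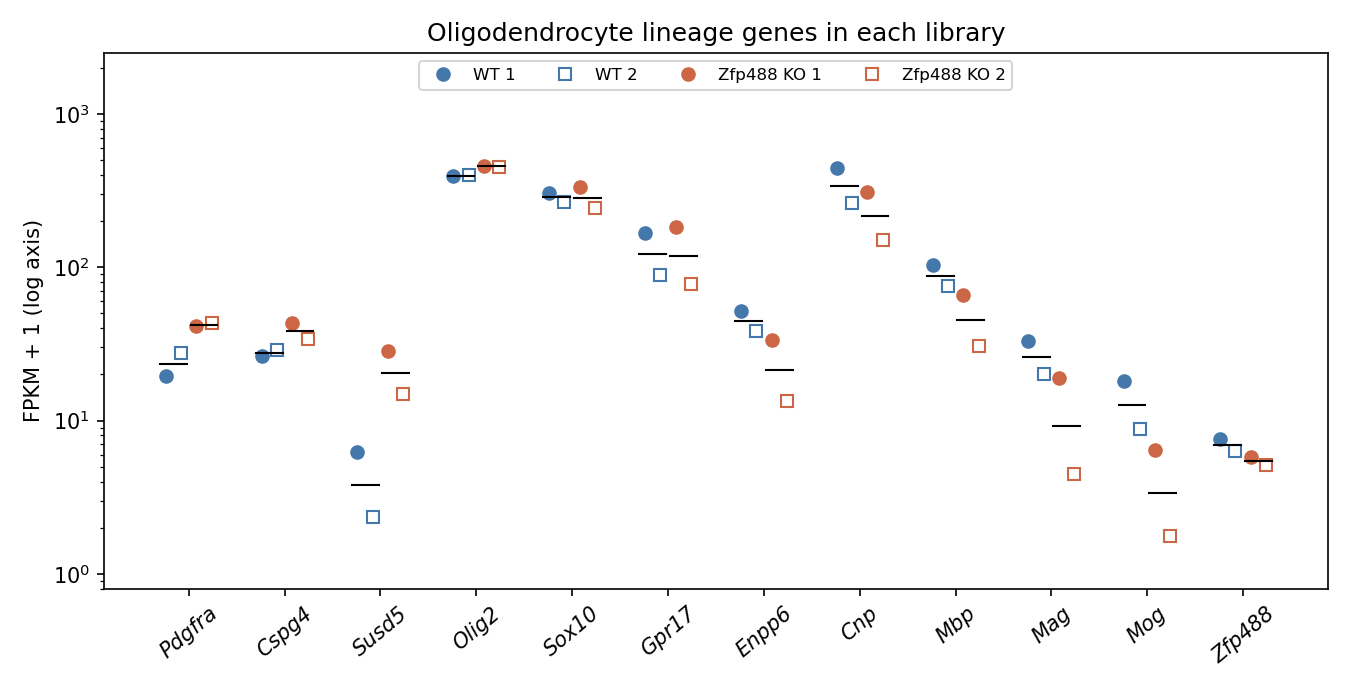
FPKM + 1 (log axis) of 12 genes of the oligodendrocyte lineage in each of the 4 libraries (blue WT, orange KO, filled circles number 1, open squares number 2, bars the means of log values over 2 libraries). Pdgfra and Susd5 were higher in both KO libraries, and Mbp, Mag and Mog were lower, none past the threshold.

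The transcription factors and chromatin regulators of the lineage did not pass as a list (24 genes, median -0.072, adjusted p = 0.829). Both KO libraries were higher for 3 of them and lower for 2. Olig1 and Olig2, basic helix-loop-helix factors that define the lineage, were at 1320 ± 101 and 394.9 ± 6.57 FPKM in WT and at 1472 ± 21.7 and 453.6 ± 0.80 FPKM in KO (SD, n = 2; log2 differences 0.16, SE 0.085, and 0.20, SE 0.099). Sox10, a factor needed for terminal differentiation, was at 286.2 ± 27.8 and 287.8 ± 64.1 FPKM, with a sign that depended on the scaling. Myrf, the factor that drives myelin gene expression, was low in all libraries (1.22 and 0.727 FPKM in WT, 1.78 and 0.323 in KO). Nkx2-2 was at 16.1 ± 7.82 and 13.5 ± 8.01 FPKM. The largest differences on this list were those of Nkx6-2, a homeobox gene of mature oligodendrocytes (9.82 and 1.96 FPKM in WT, 1.5 and 1.48 in KO; log2 difference -1.18, SE 0.68), and the deacetylase gene Sirt2 (-0.79, SE 0.44).

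Signalling lists differed in part. Notch pathway genes rose as a list (20 genes, both KO libraries higher for 8 and lower for 0, median 0.12, mean 0.29; camera adjusted p = 0.0145; adjusted p = 0.628 with an estimated correlation). Their median was at percentile 88.8 among matched random lists, and the call was lost without WT replicate 1 (adjusted p = 0.474), without KO replicate 2 (0.312) and with no filter (0.084). Dtx1, a ubiquitin ligase of the pathway, was at 2.68 ± 0.037 and 7.89 ± 2.19 FPKM (log2 difference 1.25, SE 0.35). Hey2, a transcriptional repressor induced by Notch, was at 0.371 and 0 FPKM in WT and 2.39 and 1.17 FPKM in KO. Genes of receptor tyrosine kinases and the ERK pathway rose as a list (19 genes, 2 higher, 0 lower, median 0.35; camera adjusted p = 0.038; adjusted p = 0.77 with an estimated correlation), a call that 11 of 23 alternatives ended. Without WT replicate 1 the median of that list was -0.051 (adjusted p = 0.965). Its largest differences were those of Erbb3, a neuregulin receptor (0.173 and 0.142 FPKM in WT, 1.80 and 1.68 in KO), and of the ERK target Etv5 (log2 difference 1.10, SE 0.62). The Wnt list (22 genes, 7 higher, 4 lower, adjusted p = 0.643) and the BMP and TGF-beta list (18 genes, 5 higher, 0 lower, adjusted p = 0.184) did not pass. Bambi, a decoy receptor on both lists, was at 0 and 0.195 FPKM in WT and 1.01 and 4.48 FPKM in KO. Nkd2, an antagonist of Wnt signalling, differed by -0.95 (SE 0.40), and the BMP target Id3 by 0.76 (SE 0.51).

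Glutamate receptor and ion channel genes rose as a list, with both KO libraries higher for 10 of 18 genes and lower for 1 (median 0.47; camera adjusted p = 0.0013; adjusted p = 0.656 with an estimated correlation). Kcnj16, an inward rectifier potassium channel, was at 1.10 ± 0.888 FPKM in WT and 6.01 ± 0.308 FPKM in KO (log2 difference 1.81, SE 0.44), and Kcnd2, a channel of A-type potassium currents, at 20.4 ± 0.498 and 35.4 ± 8.78 FPKM (0.75, SE 0.27). Without KO replicate 1 the list no longer passed (median 0.42, adjusted p = 0.203), and over the alternatives the median lay between 0.22 and 0.73.

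Transcripts of the cytosolic ribosome fell as a list by a small amount. Both KO libraries were lower for 43 of 54 ribosomal protein genes and higher for 0 (median -0.29; camera adjusted p = 5.0e-17; adjusted p = 0.628 with an estimated correlation). Rps23 was at 295.2 ± 34.3 FPKM in WT and 199.6 ± 15.1 FPKM in KO, and Rpl12 at 162.3 ± 18.6 and 115.8 ± 12.2 FPKM. Nuclear-encoded genes of oxidative phosphorylation were lower for 29 of 41 genes and higher for 0 (median -0.22; camera adjusted p = 6.3e-10; adjusted p = 0.45 with an estimated correlation). Among random lists matched on mean FPKM, the ribosomal median was at percentile 0 (adjusted p = 0.0011) and the oxidative phosphorylation median at percentile 4.18 (adjusted p = 0.183). Uqcrh, a subunit of complex III, was at 349.9 ± 31.7 and 240.2 ± 4.31 FPKM, and Cycs, which encodes cytochrome c, at 69.0 ± 5.31 and 49.6 ± 12.8 FPKM. Genes of the actin and microtubule cytoskeleton and of process outgrowth fell too (30 genes, 10 lower, 2 higher, median -0.19; camera adjusted p = 0.0010; adjusted p = 0.628 with an estimated correlation). Arpc1b, a subunit of the Arp2/3 complex that nucleates branched actin, was at 90.3 ± 11.8 and 47.8 ± 4.02 FPKM, and the microtubule-associated Map1b at 32.8 ± 9.14 and 17.7 ± 6.27 FPKM. The cytoskeleton median was at percentile 8.74 among matched random lists. That list did not pass without WT replicate 1 (adjusted p = 0.213), after quantile normalization (0.133) or after removal of the level trend alone (0.292). Quantile normalization and removal of the level trend also ended the call of the oxidative phosphorylation list (0.059 and 0.099). The 13 mitochondrially encoded genes fell as a list (2 lower, 0 higher, median -0.12; camera adjusted p = 0.032; adjusted p = 0.941 with an estimated correlation). Their median was at percentile 73.6 among matched random lists (95% of these between -0.282 and -0.030), so most equally abundant lists fell more. Their direction turned under 5 of 23 alternatives and without KO replicate 2 the median was 0.088. ND3 and ND4, subunits of complex I, differed by -0.35 (SE 0.15) and -0.32 (SE 0.29).

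Fold changes ran with transcript length and expression level between the genotypes. Over 6 equal groups of protein-coding genes by transcript length, the median log2 fold change was -0.18 in the shortest group (204 to 1692 bp), 0.14 in the fifth (3878 to 4893 bp) and 0.088 in the longest, and by level it went from 0.11 in the lowest group to -0.13 in the highest. In the shortest group the median was 0.041 between libraries numbered 2 and 1, and 0.0099 in the remaining split of the 4 libraries into 2 and 2. After both trends were removed, a correction chosen after seeing the data, the median of the ribosomal list was -0.10 (adjusted p = 0.0097), that of the oxidative phosphorylation list -0.044 (0.421), and that of the glutamate receptor and ion channel list 0.35 (0.016). The median of the cytoskeleton list was -0.15 (0.048), that of the mitochondrially encoded list 0.11 (0.301) and that of the receptor tyrosine kinase and ERK list 0.25 (0.071). The myelin list (-0.58, 1.2e-06) and the premyelinating list (-0.41, 0.0005) passed after the correction as before it. So did the precursor list (0.32, 4.6e-06) and the Notch list (0.19, 0.023). These calls are by camera with a preset correlation. With an estimated correlation none of the lists passed even before the correction (smallest adjusted p = 0.45).

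**Figure D2:**
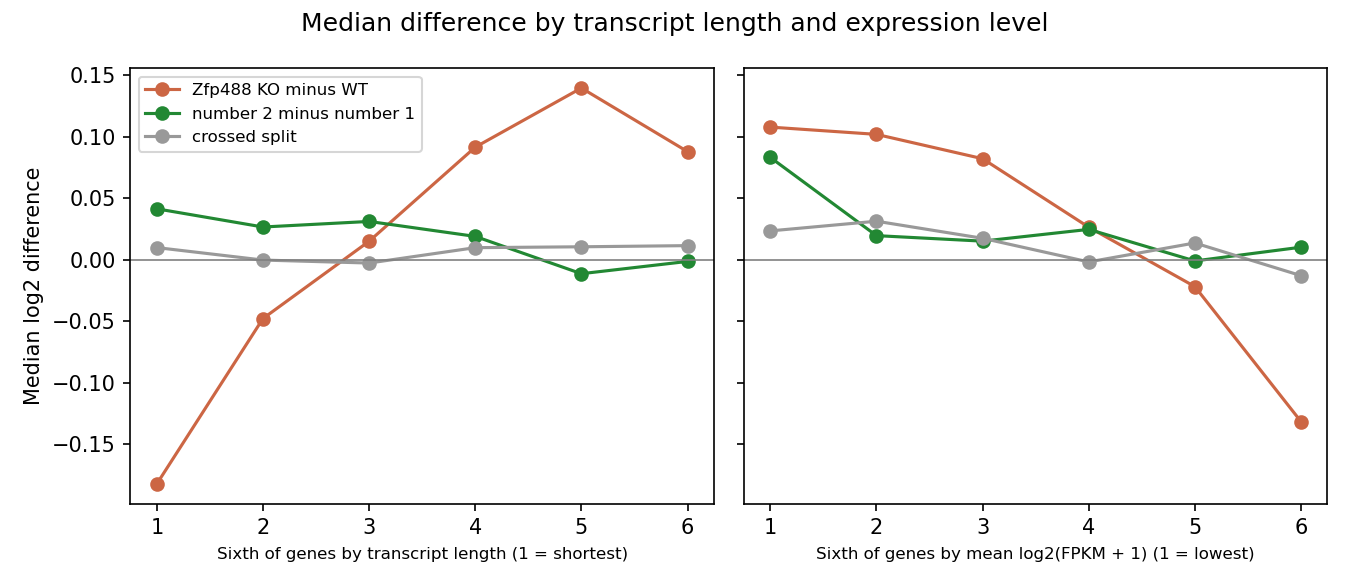
Median log2 difference of protein-coding genes in 6 equal groups by transcript length (left) and by mean log2(FPKM + 1) (right), for KO minus WT (orange), libraries numbered 2 minus libraries numbered 1 (green) and the remaining split of the 4 libraries (grey). Points are medians over about 1490 genes each, and the orange line runs from -0.18 to 0.14 with length.

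Lipid synthesis lists did not pass. Among 25 cholesterol synthesis genes, 4 were higher and 4 lower in both KO libraries (adjusted p = 0.372). Hsd17b7, an enzyme of the pathway, differed by 0.60 (SE 0.51). Among 26 fatty acid and sphingolipid genes, 11 were higher and 3 lower (median 0.16, adjusted p = 0.052). Scd1, a stearoyl-CoA desaturase, was at 0.721 and 2.81 FPKM in WT and 6.40 and 5.91 FPKM in KO, and Srebf1, a transcription factor of lipid synthesis, at 1.26 ± 0.238 and 3.75 ± 1.27 FPKM.

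The single genes with the smallest unadjusted p (0.0005 to 0.0042, limma adjusted p = 0.859 for each) were of mixed kinds. At higher levels in KO, the zinc finger gene Zcchc24 was at 27 ± 1.31 and 60.0 ± 5.29 FPKM (1.12, SE 0.20). Chaf1b, a subunit of the chromatin assembly factor CAF-1, was at 1.20 ± 0.127 and 7.43 ± 1.69 FPKM. Cachd1, Ybey and Ror2 were at most 0.345 FPKM in each WT library and between 3.43 and 5.15 FPKM in each KO library. Enpp3 (10.1 and 6.21 FPKM in KO), Zfp773 (4.15 and 5.71), Dlx2, a homeobox gene of interneurons (3.65 and 4.84), and Adm, which encodes adrenomedullin (3.38 and 2.55), were listed at 0 or at most 0.055 FPKM in WT. Rows near 0 in a single library alone were more frequent in WT (10 and 11 rows) than in KO (2 and 3). Those counts do not show how often both libraries of a group fail together. Values near 0 in both libraries of either genotype, as for the genes above and those at 0 in KO below, can still be failed estimates. At lower levels in KO, Gadd45g, a stress-inducible growth arrest gene, was at 72.6 ± 2.45 and 35.0 ± 1.01 FPKM (log2 difference -1.03, SE 0.18). Med18, a subunit of the Mediator complex, was at 14 ± 1.25 and 4.49 ± 0.305 FPKM (-1.45, SE 0.29), and Usmg5, which encodes a small protein of the mitochondrial ATP synthase, at 457.6 ± 10.7 and 317.8 ± 6.99 FPKM (-0.52, SE 0.10). Glipr2 (3.11 and 5.97 FPKM in WT), Bbs10, a chaperonin-like protein of the ciliary Bardet-Biedl group (2.92 and 2.76), and AU040972 (2.43 and 3.73) were listed at 0 in both KO libraries, and Nid1, a basement membrane protein (3.27 and 4.39), at 0 and 0.24.

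Another 6 of these 24 genes were small RNAs. Mir7025, whose locus lies within Pdgfra, was at 111 ± 14.6 FPKM in WT and 260.8 ± 15.4 FPKM in KO, and Mir6921, within Srebf1, at 9.02 ± 1.47 and 30.6 ± 1.73 FPKM. Snora52 (within Rplp2), Snora81 (within Eif4a2) and Mir1938 (within Ifrd1) were at 3.22 to 14.6 FPKM in WT and listed at 0 in both KO libraries, and Snord33 (within Rpl13a) was at 16.7 and 7.23 FPKM in WT and at 0 and 0.311 FPKM in KO. Across the 219 tested small RNA rows that lie within a single other tested gene, the fold change of the row followed that of the surrounding gene (Pearson's r = 0.574, Spearman's rho = 0.628; two-sided permutation p = 0.0001, the smallest that 10000 shuffles give). This correlation is across rows, which are not independent replicates, and it was higher for the 180 microRNA rows (r = 0.674) than for the 39 small nucleolar RNA rows (r = 0.229), a difference that was not tested.

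Lists of markers of other cell types did not pass by camera between the genotypes in the main fit. The astrocyte and radial glia list (median 0.26) passed against matched random lists (adjusted p = 0.023). By camera it passed with the replicate number as a block (adjusted p = 0.0080) and did not with an estimated correlation (adjusted p = 0.941). Neuron markers were higher in both KO libraries for 4 of 12 genes and lower for 0 (median 0.19, adjusted p = 0.052), and Stmn2, a neuronal microtubule regulator, was at 0.928 ± 0.602 FPKM in WT and 5.12 ± 2.05 FPKM in KO. Dlx2 was the only gene of that list that passed when adjusted over the list alone (0.017), and Nid1 was the only one among 14 pericyte, fibroblast and matrix genes (0.037; list adjusted p = 0.814, 2 higher and 1 lower). In every other list tested by camera, 0 genes passed when adjusted over the list alone, as over all genes. The astrocyte list (21 genes, 4 higher, 1 lower, adjusted p = 0.080; Agt -1.54, SE 1.0; Acsbg1 0.86, SE 0.46), the microglia list (22 genes, 1 higher, 0 lower, 0.814), the endothelial list (8 genes, 2 higher, 1 lower, 0.914; Esam -1.48, SE 0.67; Pltp 0.99, SE 0.67) and the red blood cell list (7 genes, 2 higher, 0 lower, 0.829; Bpgm 0.22, SE 0.18) did not pass. Alas2, of heme synthesis, was at 0 and 0.974 FPKM in WT and at 2.0 and 1.09 FPKM in KO. Fcrls and Cd68, microglial genes, were at 0 and 0.264, and at 0 and 9.62 FPKM in WT, and at 1.23 and 8.74, and at 3.17 and 12.3 FPKM in KO. Myl9, a smooth muscle myosin light chain, was at 0 and 9.65 FPKM in WT and at 4.56 and 13.4 FPKM in KO.

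The cell cycle list did not pass by camera between the genotypes (39 genes, 2 higher, 0 lower, median 0.32, adjusted p = 0.052), nor with an estimated correlation (0.924 between its genes, adjusted p = 0.941) or by fry (0.975). It passed against matched random lists (adjusted p = 0.0011), a comparison that ignores correlation between genes. By camera with the replicate number as a block it passed too (adjusted p = 3.1e-05), though the labels do not say what the number marks. Its genes also differed between the library numbers. Mki67, a marker of dividing cells, was at 0.526 and 0.527 FPKM in the libraries numbered 1 and at 4.12 (WT) and 5.92 FPKM (KO) in those numbered 2. Aurkb, a mitotic kinase, was at 0.020 FPKM in WT 1, 37.5 in WT 2, 6.67 in KO 1 and 34.6 in KO 2. The replication gene Mcm3 was at 0.009, 20.5, 13.1 and 20.7 FPKM in the same order. Both lay below 0.05 FPKM in WT 1 with at least 5 FPKM in each other library, so their WT 1 values can be failed estimates. Number 2 libraries were higher than number 1 libraries by a median of 1.76 on the log2 scale over the cell cycle list, 1.86 over the microglia list, 1.33 over the pericyte, fibroblast and matrix list, 1.05 over immediate early genes, 0.81 over the astrocyte list, 0.74 over the red blood cell list and 0.46 over the receptor tyrosine kinase and ERK list. They were lower by medians of -0.63 over the myelin list and -0.67 over the premyelinating list, and the precursor list differed by -0.028. These 9 lists passed by camera (adjusted p between 1.9e-29 and 0.0086, the precursor list apart, at 0.721), and 0 passed with an estimated correlation (smallest adjusted p = 0.312). With genotype in the model, 41 genes differed between the numbers by limma at adjusted p under 0.05, 39 of them higher in number 2, and 0 genes did without it (1172 at unadjusted p under 0.05). Among the 41 were Egr1, an immediate early transcription factor (log2 difference 3.89, SE 0.25), the endothelial tight junction gene Cldn5 (4.76, SE 0.37), Ttr, a transthyretin gene of the choroid plexus (3.63, SE 0.26), the microglial complement gene C1qb (2.17, SE 0.24) and Cdk1, the mitotic kinase (2.40, SE 0.22).

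**Figure D3:**
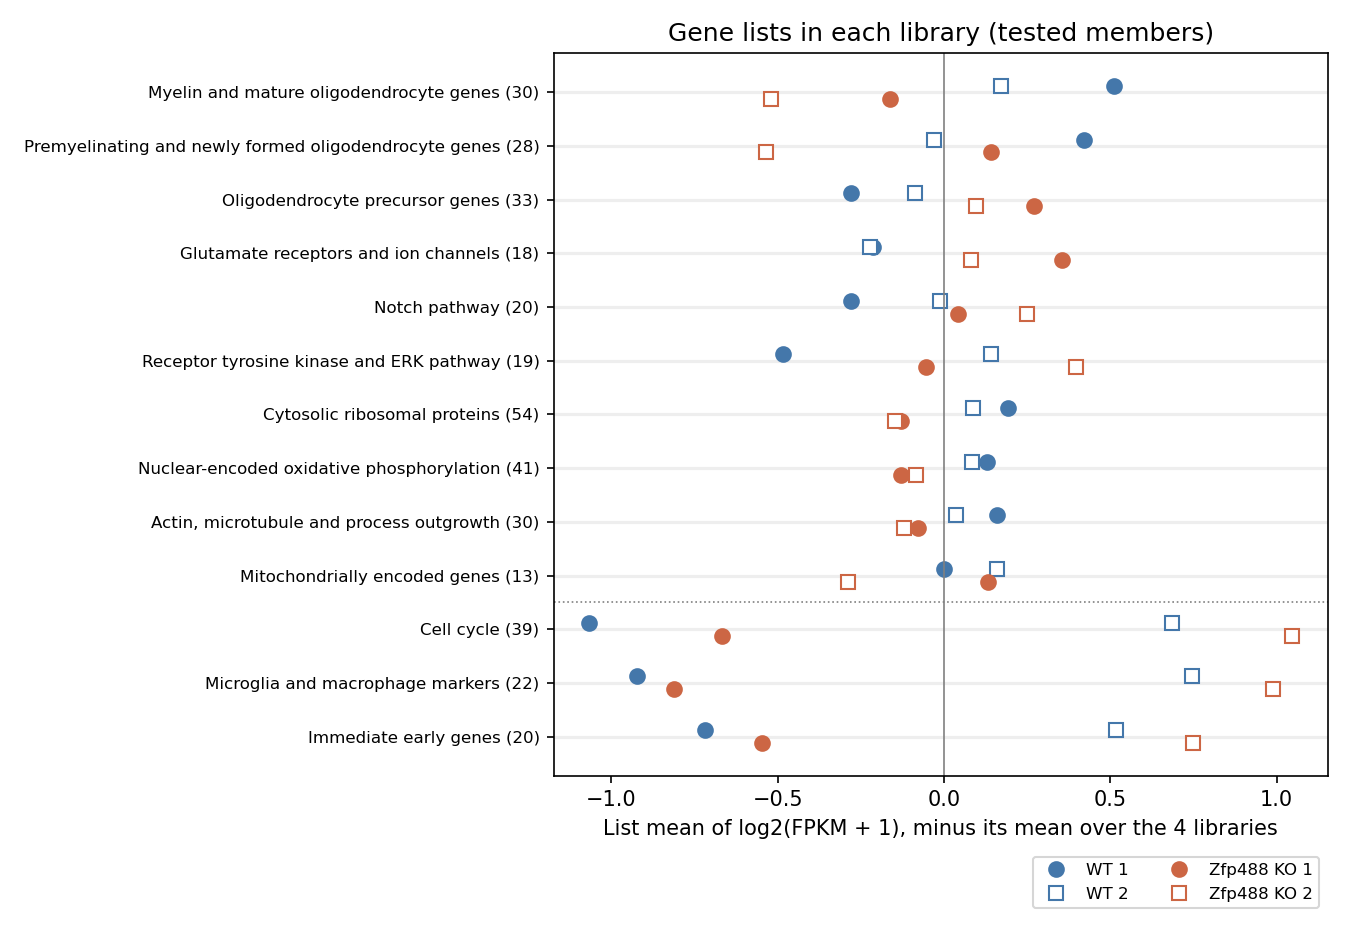
Mean log2(FPKM + 1) of the tested members of 13 gene lists in each library, minus its mean over the 4 libraries (blue WT, orange KO, filled circles number 1, open squares number 2, number of genes in parentheses). The 10 lists above the dotted line passed by camera between the genotypes, and the 3 below it separated the libraries by number. Of the 10, the myelin, premyelinating, and receptor tyrosine kinase and ERK lists also passed by camera between the numbers.

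Stress and response lists did not pass between the genotypes. These were immediate early genes (20 genes, 2 higher, 0 lower, adjusted p = 0.486), heat shock proteins and chaperones (20 genes, 1 higher, 2 lower, 0.829), the unfolded protein and integrated stress response (23 genes, 4 higher, 8 lower, 0.904), hypoxia and glycolysis (22 genes, 5 higher, 6 lower, 0.862), the interferon response (13 genes, 1 higher, 2 lower, 0.686) and the p53 response (15 genes, 2 higher, 3 lower, 0.904). Ankrd37, a hypoxia-inducible gene, was at 3.64 and 9.65 FPKM in WT and 0.729 and 1.88 FPKM in KO, and Irf1, an interferon-induced factor, at 1.20 ± 1.14 and 3.63 ± 0.24 FPKM. Perp, a p53 target, was at 0.311 and 0 FPKM in WT and at 1.58 and 2.03 FPKM in KO. Fos was at 7.71 and 70.2 FPKM in WT and 0.862 and 54.8 FPKM in KO, following the library numbers, and Ier5 at 0 and 5.31 and at 7.15 and 6.32 FPKM. Ddx58, an RNA sensor, was at 1.76 and 0 FPKM in WT and at 2.47 and 1.33 FPKM in KO. Log2 differences were -0.66 (SE 0.66) for the small heat shock protein gene Cryab, -0.66 (SE 0.76) for Hspa4l, 0.59 (SE 0.39) for Aldh1l2, -0.58 (SE 0.43) for Mthfd2 and 0.87 (SE 0.94) for Gtse1. The median and the mean had opposite signs in the red blood cell list (-0.13 and 0.060), the heat shock list (0.024 and -0.037), the p53 list (-0.059 and 0.073) and the endothelial list (0.0077 and -0.0019).

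Lists with fewer than 5 tested genes were not tested as lists. Of the ependymal and choroid plexus markers, Ttr was at 4.97 and 94.6 FPKM in WT and at 11.9 and 122 FPKM in KO, Rsph1 was listed at 0 in both libraries numbered 1 and stood at 1.86 and 4.41 FPKM in the others, and Sostdc1 lay between 6.70 and 11.6 FPKM. Of the sex-linked genes, Xist lay between 1.08 and 1.71 FPKM and the Y-linked Eif2s3y between 0.72 and 1.79 FPKM, so transcripts of both sexes were read in every library. Tsix, antisense to Xist and not told apart from it without the strand setting, lay between 5.08 and 8.11 FPKM. The Y-linked Ddx3y, below the filter, was at 2.205 and 0.451 FPKM in WT and at 0.779 and 0.24 FPKM in KO. An equal share of the sexes is therefore not shown. Of 14 listed neighbours of Zfp488 on chromosome 14, Vstm4 alone was expressed highly enough to be tested (32856756 to 32939491). It was at 0.66 and 0.038 FPKM in WT and 3.81 and 4.25 FPKM in KO (log2 difference 1.94, SE 0.41; limma adjusted p = 0.859).

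By camera with a preset correlation, 10 of the 28 tested lists passed at adjusted p under 0.05, 4 higher and 6 lower, and 0 passed with an estimated correlation (smallest 0.45) or by fry, which asks whether a list's genes move one way on balance (smallest adjusted p = 0.287). Against 10000 random lists matched on mean FPKM, which ignore correlation between genes, 8 lists passed, 6 of them shared with the 10 and the other 2 the cell cycle and astrocyte lists. For 1780 genes both KO libraries lay above both WT libraries and for 1969 below, 34.9% of tested genes, where chance gives 33.3%.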

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

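The fits that removed trends, small RNA rows or the genes of 6 other lists, and the correction of the block fit for trends, were chosen after the result was seen, and the other alternatives were planned. The count of single genes past the threshold was 0 by limma in every alternative run. Over the values recomputed, 2219 kept their direction and side of the threshold, 41 kept their direction but no longer passed, 4 moved by more than the spread or the allowed ratio, and 44 changed direction. Depth limits the low genes: on 1 kb, 1 FPKM stood for 38.1 to 43.7 reads, so values under 0.0229 FPKM lie below 1 read there. The count of gene lists past the threshold was 10, and between 7 and 15 when 1 library was left out, where a lone library is assumed to vary like the other group. It was 0 with a correlation estimated from the data and 0 by fry, against 10 by camera. The cause was not tested beyond simulated lists. There the estimated correlation called 0% of those shifted, and camera, with genes correlated at 0.13, 12.6% of those unshifted. The premyelinating and mitochondrially encoded lists had higher estimates (0.478 and 0.792), so 12.6% is no error rate for them. For the oxidative phosphorylation and Notch lists the estimates were -0.0088 and -8.6e-05, below the preset 0.01. A higher correlation between genes therefore does not account for the loss of those 2 calls with the estimate. With the replicate block 12 lists passed, all 10 among them, the other 2 being the cell cycle (adjusted p = 3.1e-05) and astrocyte (0.0080) lists, and 0 genes passed by limma (1025 at an unadjusted p under 0.05, smallest adjusted p = 0.413). The labels do not say what the numbers mark: same-numbered libraries deviated together (correlation over genes 0.289), and the first principal component (47.4% of the variance) separated the numbers. The second component (29.0%) separated the genotypes. The difference in the maturation index was -1.40 with a pseudocount of 0.1, and between -1.27 and -0.64 when 1 library was left out. The cause was not tested for these, nor for the changes of direction that follow. The Zfp488 difference kept its direction in every alternative run, between -0.48 and -0.21 when 1 library was left out.

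Left-out libraries turned the direction of genes that had not passed. The log2 difference lay between -0.30 and 4.11 for Mcm3, -1.22 and 4.02 for Aurkb, -0.66 and 1.31 for Mki67, -0.51 and 2.90 for Cd68, -0.25 and 3.16 for Myl9, -1.26 and 2.74 for Ttr, -0.30 and 1.68 for Rsph1, and -3.74 and 1.16 for Fos. It lay between -1.48 and 0.16 for Cryab, -1.69 and 0.38 for Hspa4l, -0.73 and 0.078 for ND4, -0.18 and 1.92 for Gtse1, -0.25 and 0.33 for Tsix, -0.21 and 0.51 for Myrf, -0.23 and 0.22 for Sox10, -0.88 and 0.31 for Nkx2-2, and -0.65 and 0.59 for Gpr17. The median of the mitochondrially encoded list lay between -0.35 and 0.088. That median was 0.033 with the length trend removed, 0.086 with the level trend removed and 0.11 with both, with or without the replicate block. Tsix was at -0.11 with the length trend removed, -0.0081 with the level trend, -0.099 with both, with or without the block, and -0.011 with the GC trend. Sox10 was at 0.093 after rescaling to TPM, 0.023 with median-ratio scaling, 0.17 with quantile normalization, 0.16 with the level trend removed, 0.067 with both trends, with or without the block, and 0.0030 with the GC trend. Gpr17 was at 0.067 in TPM, 0.080 with quantile normalization and 0.093 with the level trend removed.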

Other observations

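The tests by camera and with an estimated correlation between the genotypes were planned, and the tests of explanations, those between library numbers and those after a correction for trends were chosen only after the result was seen. Among the 41 genes that differed between library numbers by limma with genotype in the model, named here after their values were seen, 8 were on the cell cycle list and 6 were histone genes. Higher in number 2 were the mitotic genes Ube2c (log2 difference 2.09, SE 0.15), Cdc20 (2.13, SE 0.17) and Ccnb1 (2.53, SE 0.25), the microtubule regulator Stmn1 (1.69, SE 0.10) and Fabp7, a fatty acid binding protein of radial glia and precursors (0.82, SE 0.069). The amino acid transporter gene Slc38a5 (4.11, SE 0.38), the phosphatase gene Dusp1 (3.51, SE 0.36) and Spp1, which encodes osteopontin (3.37, SE 0.38), were also higher. Lower were Arsb, a lysosomal sulfatase (-1.54, SE 0.14), and Cd9, a tetraspanin of differentiating oligodendrocytes (-0.65, SE 0.066).

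Lower myelin and higher precursor genes in the KO libraries may reflect a less mature population of sorted cells, a hypothesis found and tested on the same data. A lower share of lineage cells would lower Olig1, Olig2 and Sox10, factors made throughout the lineage, about as much as the myelin list (median -0.59, interval over genes -0.95 to -0.35). Their mean difference was 0.117 (interval over libraries -0.191 to 0.426), so these factors did not fall on average. The myelin interval does not measure the spread between libraries (list means 4.13 and 3.79 in WT, 3.46 and 3.10 in KO). The comparison therefore cannot decide whether a lower share was the whole cause. The shift between library numbers, scaled to the myelin change, would raise the cell cycle list by 1.64. The observed median of 0.32 differed from that by -1.32 (interval over genes -4.25 to -0.635). Genes of that list were correlated at 0.924, and its library means were 2.51 and 4.26 in WT and 2.91 and 4.62 in KO. An interval over genes therefore cannot decide whether that shift was the cause. Each genotype held 1 library of each number, so an equal shift by number cancels between genotypes. Fold changes by genotype and by number correlated at 0.060 across genes. The precursor list differed by -0.028 between numbers and by 0.35 between genotypes (library means 4.84 and 5.03 in WT, 5.39 and 5.21 in KO). This argues against that shift as the source of the higher precursor list. An unequal shift in the myelin list stays undecided. Both the myelin and the precursor list passed by camera after the length and level trends were removed (larger adjusted p = 4.6e-06). With an estimated correlation neither passed even before that correction (adjusted p = 0.628 for each). Of the 3 splits of the 4 libraries, 1 called as many as 10 lists, the real one, and the highest of the others called 9, the split by library number, which are too few splits for a share under 0.05. Whether fewer cells matured in the KO cortex or the gate took in earlier cells was not tested and stays open. So do a lower share of lineage cells and what the estimated correlation leaves undecided.

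Ribosomal, oxidative phosphorylation and channel lists differ in transcript length and level, so a technical trend with these could have produced their calls. For the oxidative phosphorylation list the trends account for most of the difference: its median went from -0.22 to -0.044 (interval -0.061 to -0.0052) once both were removed and the call ended because the difference shrank (adjusted p = 0.421). The ribosomal list kept a median of -0.10 (interval -0.14 to -0.053) from -0.29, so the trends account for most of its difference too, but it still passed by camera (adjusted p = 0.0097). The channel list kept 0.35 (interval 0.11 to 0.44) from 0.47 (adjusted p = 0.016). Lengths were those of the longest annotated transcript, 2863 bp for Rpl12, so the removal of the length trend can be incomplete. What remained therefore does not decide whether the trends were the whole cause for either list. Neither list passed by camera with an estimated correlation even before the correction (adjusted p = 0.628 and 0.656). Genes on none of the lists showed the same slope, from -0.17 in the shortest group to 0.14 in the fifth. What made the trends, in the libraries or in the cells, was not tested.

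The libraries numbered 2, of both genotypes, may have held more dividing cells and microglia, but no label says how they differed. A lower share of lineage cells, with the mix of the other cells unchanged, would raise the markers of other types alike. The microglia median exceeded the neuron median by 1.68 (interval 1.0 to 2.3, over genes and not libraries). An interval over genes, with that assumption, cannot decide whether the share of lineage cells was the cause. A change in the types that rose stays open too. Of the factors made throughout the lineage, Olig1 and Olig2 differed by 0.093 and 0.015 between the numbers, and Sox10 by -0.33. Of the microglial genes C1qb differed by 2.17 (SE 0.24), and Cx3cr1 was at 0.012 and 0.588 FPKM in the libraries numbered 1 and at 2.86 and 4.0 FPKM in those numbered 2. The O4 and GalC gate should exclude microglia. Apart from the share of lineage cells no explanation was tested, since the design names no group by number.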
